A study of Arabidopsis thaliana with 6 samples.

How the data were processed

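The series holds 6 Arabidopsis thaliana RNA libraries from dissected embryos and seed coat. Per the labels' protocols, total RNA was extracted with a PicoPure kit and amplified linearly with NuGEN's WT-Ovation Pico system. Second strands were made after poly-A tailing, the cDNA was sheared, and SOLiD adaptors were ligated before PCR enrichment and size selection on a gel. Amplification and PCR copies carry no molecular identifiers, so reads are not independent molecules. The protocol in the labels does not state that strand was kept, so genes that overlap an antisense gene are called uncertain.

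Per the file headers, the deposited values are read counts per transcript, 1 entry per isoform, with the covered bases and the length of each transcript beside them. The counts are whole numbers in WT library 7, kyp library 11, the globular library and the seed coat library. In WT library 11 and kyp library 12, whose names carry the prefix MC, the deposited values were treated as estimated counts: 12.7% and 10.8% of transcripts end in a fractional read of 0.5. They were rounded to whole numbers, fractional reads upward, and how the authors made them is not given in the sources used here. The share of such values in transcripts with at least 50 reads was 4.81% on chromosome 4 and 18.9 to 31.8% on the other chromosomes in WT library 11. The aligner, the counting tool, the genome build and the annotation are likewise not given in the sources used here. No build is named, so no coordinates are printed, and the RefSeq annotation of TAIR10.1 served only for names, products, biotypes, neighbouring genes and shared sequence. Of 32140 loci, 31584 had an entry in it. The files hold no reads split by parental allele, so a planned share of maternal reads was not computed.

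The 37813 transcripts present in all 6 files were used, and 5 present in only some were left out. Reads shared by isoforms are counted in each isoform, so each locus was represented by its isoform with the most reads over the 6 libraries. Gene totals ranged from 1448503 to 4107228 reads, and the 10 genes with the most reads took 3.75 to 11.9% of a library. The median covered share of transcript length in genes of similar depth and length was 59.8 to 67.4%. Groups came from the titles and the maternal genotype in the labels. Sample numbers in the titles name libraries and do not pair them.

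Genes were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood F tests and Benjamini-Hochberg adjustment at 0.05. Every adjusted p given for a gene is from this test unless another tool is named. The kyp comparison used the 4 libraries of 2-4 cell embryos. The globular and seed coat comparisons used all 6 libraries in 4 groups, so that the lone libraries borrow the spread of the 2-4 cell pairs, with 2 residual degrees of freedom. The 2 comparisons share the WT libraries, so their agreement was not tested. Standard errors are the size of the log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 0.475 in the kyp comparison and 0.505 in the others. Levels are TMM-scaled CPM, except that the summed list levels and the ratios to the seed coat library use CPM of the gene totals. A fold against a group without reads is a lower bound set at 3 reads per library, and with 1 to 3 reads in a group the ratio of summed reads is given with an exact Clopper-Pearson counting interval.

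Gene lists were fixed before the data were examined: flavonoid pathway, ovule integument, endosperm and imprinted genes, embryo patterning, H3K9 and DNA methylation machinery, CAF-1 and Polycomb complexes, known methylation targets, cell cycle, photosynthesis, heat shock, wounding with touch and jasmonate, seed storage, pollen and sperm, and reference genes. All 292 members had a locus in the files. The classes of 315 ribosomal protein loci, by product name, and 3909 loci of pseudogene biotype, which include transposons, came from the annotation. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. With a correlation estimated at 2 residual degrees of freedom no list call held. That setting was not run on simulated lists, so whether it can call a changed list here was not tested. The fry test, of whether a set moves on balance in one direction, passed for the wounding list in the globular comparison (adjusted p = 0.015) and for no other list.

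The rule for named genes was also fixed in advance. It took KYP, then per comparison and direction up to 10 genes with the largest fold change among those past the threshold with at least 20 mean reads and no overlap between groups, filled up by p where fewer passed and then given as values. It added up to 4 members per list, those past the threshold or otherwise the 2 with the highest mean level. The LAT52-like gene is AT5G45880. Of 117 named loci, 10 are uncertain because over 10% of their exons overlap another gene or over 20% of their 35-base windows occur elsewhere.

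Alternatives were DESeq2's size factors, the DESeq2 1.42.0 Wald test, no low-count filter, a filter of 5 CPM, the name prefix as a block, rRNA left out, thinning to equal depth, the legacy robust quasi-likelihood fit, each 2-4 cell library left out in turn and, for kyp, all 6 libraries. Fits with a 2-4 cell library left out take their spread from the other pair alone, so their counts are not on a par with the main ones. The first isoform of a locus and the sum over isoforms were added after the data were seen. Counts were simulated with the fitted trend of spread, and 50 genes of at least 20 mean reads were changed per fold size. Genes with fewer reads were not among those changed, so the shares do not cover them. For the kyp comparison (15997 genes) edgeR called 4% of 2-fold, 28% of 4-fold, 68% of 8-fold and 86% of 16-fold changes, and 6 of 14931 unchanged genes (13 by DESeq2). In the globular comparison (17706 genes) the shares were 2%, 10%, 52% and 78% with 0 of 16687 unchanged genes called (12 by DESeq2), and in the seed coat comparison 2%, 12%, 50% and 80% with 2 of 16748 (7 by DESeq2). A simulated list of 30 genes changed 2-fold was called by camera in each comparison, and 0 of 20 unchanged lists were. The simulated genes were drawn independently, so this does not show how often camera calls unchanged lists of correlated genes. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 served for the joins and intervals.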

Results

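RNA was measured by SOLiD sequencing in 6 libraries made from hand-dissected Arabidopsis thaliana seed tissues, each from linearly amplified total RNA. Wild-type embryos came from Landsberg erecta (Ler) mothers crossed with Columbia (Col) fathers, with 2 libraries at the 2-4 cell stage (WT libraries 7 and 11) and 1 at the globular stage. A further 2 libraries held 2-4 cell embryos whose Ler mother, by the maternal genotype label, carried kyp-2, a mutant allele of KRYPTONITE, the enzyme that methylates histone H3 at lysine 9 (kyp libraries 11 and 12). The last library was the Ler seed coat, the maternal tissue around the embryo, at the 2-4 cell embryo stage. Reads assigned to genes numbered 2497236 and 3906315 in WT libraries 7 and 11, 1448503 and 4107228 in kyp libraries 11 and 12, 1773576 in the globular library and 1935907 in the seed coat library. Between 17835 loci (globular) and 20677 loci (seed coat) had a read. Ribosomal RNA took 8.999% of the reads in WT library 11 (95% Clopper-Pearson interval 8.97 to 9.03%) and between 0.804% (0.793 to 0.815%) and 1.80% (1.78 to 1.82%) in the other libraries. The labels do not say that the libraries of a group came from separate plants, so the p-values measure the spread between these samples, which may be technical. Read intervals and floors cover the counting error of reads only. They treat amplified copies as independent, so the error for molecules may be larger.

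Transcripts of KYP (AT5G13960) were present in every library. There were 134 and 224 reads in WT libraries 7 and 11, 67 and 167 in kyp libraries 11 and 12, 44 in the globular library and 77 in the seed coat library. The level was 58.6 ± 3.74 CPM (read counts scaled to library size; SD, n = 2) in WT and 41.7 ± 2.86 CPM (n = 2) in kyp embryos. The log2 fold change of −0.50 (SE 0.42) did not pass the test (edgeR adjusted p = 1). The labels of the kyp libraries are not uniform: their titles give the cross in the same words as for WT, with kyp only in the sample name, and kyp library 11 has a maternal genotype label of wild type beside that of kyp-2. The KYP level does not settle the genotype, and the counts do not tell parental copies apart.

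The comparison of kyp with WT 2-4 cell embryos asked which transcripts differ when the mother lacks normal KYP. Of 15997 genes tested, 3 rose and 2 fell. A locus annotated as a pseudogene, AT2G20460, had 1 read in each WT library and 52 and 194 reads in the kyp libraries. This was a ratio of 130 (95% counting interval 35.5 to 1076; log2 fold change 6.74, SE 0.87, edgeR adjusted p = 0.0185). The gene of an SRP54 subunit of the signal recognition particle, AT5G49500, was at 84.8 ± 39.6 CPM in kyp against 3.79 ± 0.0489 CPM in WT (n = 2 each; log2 fold change 4.47, SE 0.57, edgeR adjusted p = 0.0185). The cysteine proteinase gene AT3G43960 was at 419 ± 150 CPM in kyp and 21.6 ± 10.5 CPM in WT (4.26, SE 0.49, edgeR adjusted p = 0.0103). Among the genes that fell, AT5G49180, of the plant invertase and pectin methylesterase inhibitor family, was at 19.5 ± 3.63 CPM in kyp and 577 ± 16.6 CPM in WT (−4.87, SE 0.42, edgeR adjusted p = 0.00138). The lipid-transfer protein gene AT1G62500 was at 2.37 ± 0.333 CPM in kyp and 105 ± 30.2 CPM in WT (−5.48, SE 0.56, edgeR adjusted p = 0.00433).

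Other genes with small p-values did not pass the threshold. The pseudogene loci AT1G64270 and AT5G38035 had ratios of 245 (counting interval 43.6 to 9732) and 215 (38.1 to 8526), each with an edgeR adjusted p of 0.0618. AT3G29078 and AT2G21310, without reads in WT, were at least 38.9-fold and 18.3-fold higher in kyp against a floor of 3 reads per library. The nitrate transporter gene NRT1.7 had 1 read in WT and a ratio of 152 (26.8 to 6030.3; edgeR adjusted p = 0.0795). The receptor kinase gene AT1G69990 had a ratio of 104 (35.1 to 505; edgeR adjusted p = 0.0825). LHCA3, a light-harvesting protein of photosystem I, had a log2 fold change of 2.87 (SE 0.48, edgeR adjusted p = 0.0936). On the lower side stood the extensin-like gene AT3G49270 (log2 fold change −2.41), the disease resistance gene AT5G41750 (−3.74), the inositol phosphorylceramide synthase gene AtIPCS1 (−2.66) and AT1G56660 (−2.11). So did the TRAF-like gene AT3G58200 (−3.64), BAP1 (−1.93) and AT2G27080 (−1.83). 4CL8 was at least 19.0-fold lower in kyp. At an unadjusted p under 0.05 there were 465 genes higher and 350 lower. The DESeq2 Wald test called 33 higher and 17 lower. Counts moved with each library left out: 4 higher and 4 lower without WT library 7, and 17 and 13 without kyp library 11. They were 87 and 41 without WT library 11 and 78 and 48 without kyp library 12. A fit with a library left out has a single library in that group and takes its spread from the other group alone. Its counts are therefore not on a par with those of all 4 libraries. With the libraries thinned to equal depth AT2G20460 no longer passed (edgeR adjusted p = 0.067).

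**Figure D1:**
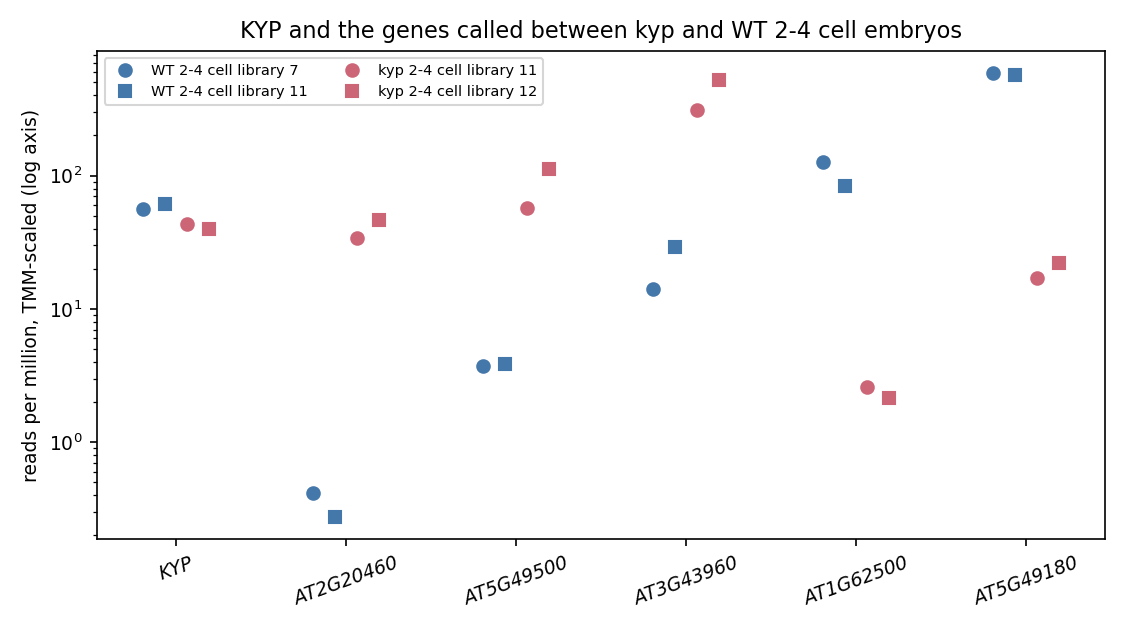
TMM-scaled CPM, on a log axis, of KYP and the 5 genes called between kyp and WT 2-4 cell embryos, 1 point per library, circles for the libraries without the MC prefix and squares for those with it. AT5G49180 had a mean of 577 CPM in WT and 19.5 CPM in kyp, and KYP 58.6 and 41.7 CPM.

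By list, each of the 38 tested nuclear photosynthesis genes had a positive fold change in kyp, with a median log2 of 1.28. The list rose (camera adjusted p = 5.3e-18; adjusted p = 0.47 with an estimated correlation). RBCS1A, the small subunit of Rubisco, was at 615 ± 270 CPM in kyp and 302 ± 112 CPM in WT, and PSBW of photosystem II at 469 ± 349 and 239 ± 39.7 CPM (n = 2 each). No photosynthesis gene passed the edgeR threshold over all genes tested, against 17 at an unadjusted p under 0.05, 2 by DESeq2 and 3 adjusted over the list alone. Without kyp library 11 the median was 0.30 with 27 positive and 10 negative members (camera adjusted p = 0.018). Summed photosynthesis levels were 7143 CPM in kyp library 11 and 2588 CPM in kyp library 12. They were 1787 and 2141 CPM in WT libraries 7 and 11 and 9033 CPM in the seed coat library. Outside this list, each of the 22 tested genes called higher in the seed coat library had a positive fold change in kyp, with a median log2 of 2.40 (2.95 for kyp library 11 over WT library 7 and 0.47 for kyp library 12 over WT library 11). Both comparisons share the WT libraries, and of 48 genes called higher in the globular library 35 were positive in kyp, with a median of 0.59. Another set, 511 tested genes over 8-fold higher in the seed coat than in the globular library, was chosen without the WT libraries. In kyp 320 of these were positive, with a median of 0.35 (0.66 for kyp library 11 over WT library 7 and 0.01 for kyp library 12 over WT library 11). The 8 tested heat shock genes all had negative fold changes, with a median of −1.39. The list fell (camera adjusted p = 1.5e-09; adjusted p = 0.36 with an estimated correlation). HSFA2, a heat shock transcription factor, was at 144 ± 77.7 CPM in kyp against 408 ± 129 CPM in WT. The chaperone gene HSP70-4 was at 90.6 ± 6.46 against 230 ± 62.9 CPM. By edgeR none of the 8 passed over all genes, 7 had an unadjusted p under 0.05, DESeq2 called 0, and 7 fell when adjusted over the list alone. Of 15 wounding, touch and jasmonate genes 12 had negative fold changes, with a median of −0.69. The list fell (camera adjusted p = 2.2e-04; adjusted p = 0.36 with an estimated correlation). Of its members DREB2A, a drought and heat transcription factor, was at 157 ± 33.2 CPM in kyp and 375 ± 39.4 CPM in WT. TCH2, a calmodulin-like gene that overlaps an antisense gene and is uncertain, was at 637 ± 8.65 and 969 ± 40.0 CPM. By edgeR 0 of these 15 passed over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05 and DESeq2 called 0.

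Pseudogene and transposon loci had 107 tested members, 64 with positive and 43 with negative fold changes. Their median log2 fold change was 0.20 and their mean 0.97. The class rose (camera adjusted p = 0.0010; adjusted p = 0.41 with an estimated correlation). Of these loci 1 rose over all genes tested, and 14 rose and 4 fell when adjusted over the list alone. DESeq2 called 9 higher and 1 lower. The camera call was lost without WT library 7 (median 0.35, adjusted p = 0.070) and without kyp library 12 (median −0.06, adjusted p = 0.85). The median was 0.54 without kyp library 11 and 1.83 without WT library 11, and the class stayed past the threshold in both. It also did so without a low-count filter (median 1.47, 263 positive and 145 negative) and in the fit over all 6 libraries (median 0.49).

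The lists nearest to KYP function did not pass. The machinery of H3K9 and DNA methylation, small RNAs and demethylation had a median of −0.28 over 29 genes (camera adjusted p = 0.14), and of −0.51 without kyp library 11. AGO4, an effector of RNA-directed DNA methylation, was at 166 ± 44.7 CPM in kyp and 202 ± 1.02 CPM in WT. Known targets of DNA and H3K9 methylation had a median of 0.38 over 5 tested genes, a sign opposite to the camera direction (adjusted p = 0.92). With 1 library left out that median lay between −0.04 (without kyp library 12) and 0.67 (without WT library 11), at 0.02 without WT library 7 and 0.04 without kyp library 11, and it was 0.02 with the name prefix as a block. IBM1, a H3K9 demethylase gene, stood at 36.4 ± 11.2 CPM in kyp and 63.7 ± 20.9 CPM in WT. CAF-1 and Polycomb complexes (median 0.15, camera adjusted p = 0.26), cell cycle and DNA replication genes (−0.13, 0.31) and reference genes (−0.11, 0.91) did not pass either. Embryo patterning regulators had a median of −0.18 (camera adjusted p = 0.33), which was −0.32 without kyp library 11 and 0.11 without WT library 11. Ribosomal protein genes had a median of −0.13 (0.14, and 0.0062 without kyp library 11). For endosperm and imprinted genes the median was 0.31 (camera adjusted p = 0.14). It moved to 0.05 without kyp library 11, 0.92 without WT library 7 and 0.83 without WT library 11. The median was 0.25 for ovule integument genes (camera adjusted p = 0.18) and −0.03 for flavonoid genes (0.62). For flavonoid genes its sign turned with the library left out: −0.34 without WT library 11, 0.40 without WT library 7 and 0.08 without kyp library 11. In these 10 lists edgeR called 0 genes over all genes tested or adjusted over the list alone, and DESeq2 called 0. At an unadjusted p under 0.05 the counts per list lay between 0 and 3 higher and 0 and 2 lower. No seed storage or oil body gene had enough reads to be tested in this comparison. Pollen and sperm genes had 2 tested members, VGD1, a pectin methylesterase of pollen (log2 fold change 2.24), and a LAT52-like pollen gene (5.19), too few for the list test. Over all genes tested edgeR called neither, both had an unadjusted p under 0.05, DESeq2 called 1, and both passed when adjusted over the list alone.

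**Figure D2:**
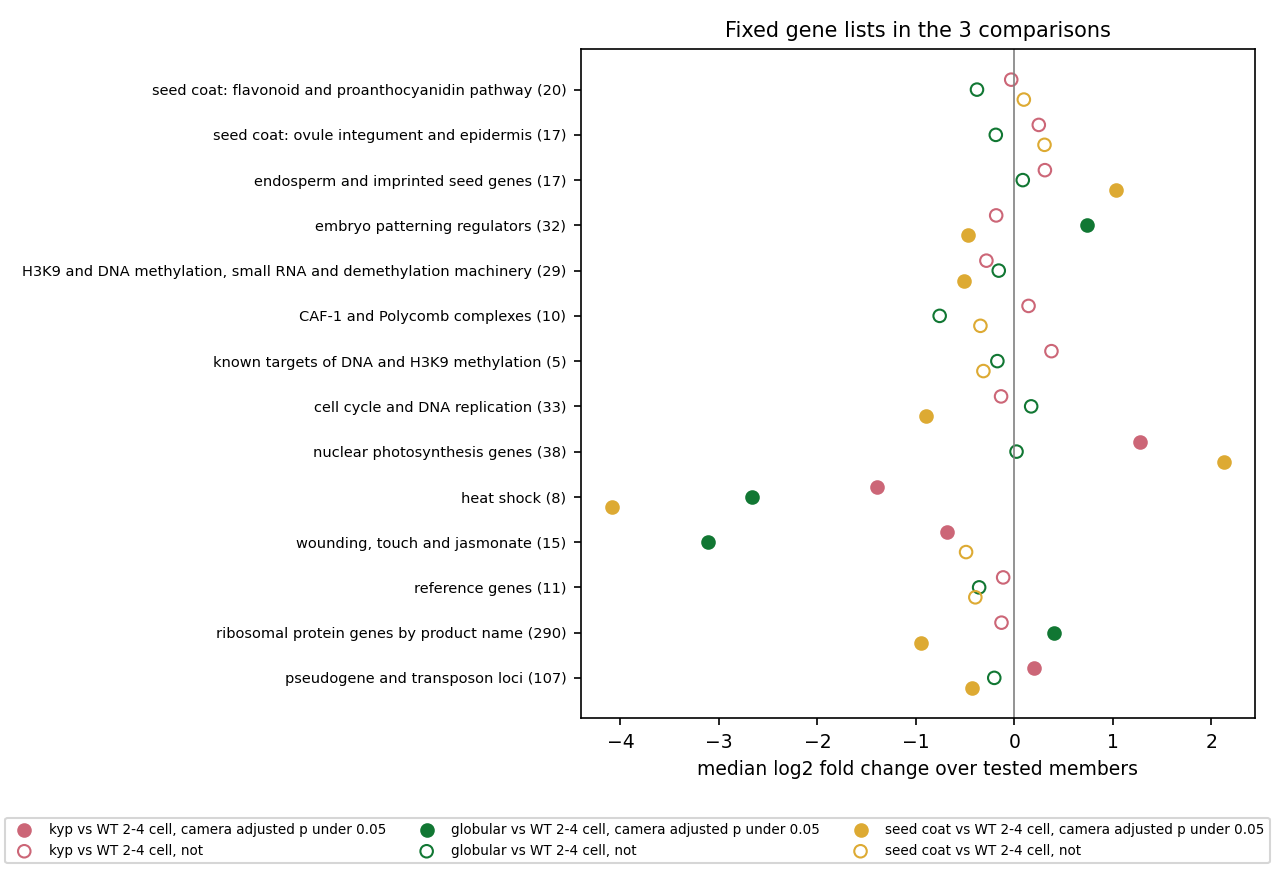
Median log2 fold change over the tested members of each gene list in the 3 comparisons with WT 2-4 cell embryos, with filled points where camera's adjusted p was under 0.05 and the number tested in the kyp comparison in brackets. The photosynthesis list stood at 1.28 in kyp and 2.13 in the seed coat, and the heat shock list at −1.39 in kyp, −2.67 in globular embryos and −4.09 in the seed coat.

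The 4 libraries of 2-4 cell embryos fall into a pair with the name prefix MC (WT library 11 and kyp library 12) and a pair without it. The kyp minus WT difference was therefore also taken within each pair. Across 15997 genes, which are not independent replicates, the differences of both pairs had a Pearson correlation of 0.0517, a Spearman correlation of 0.0216 and the same sign in 50.5% of genes. With the pairs crossed the Pearson correlation was −0.0394, and −0.165 over genes with a mean of at least 50 reads. In simulated libraries the uncrossed value was 0.0086 without any changed gene and 0.0860 with 230 genes changed. Each pair holds 1 library per group and gives no test of its own. With the prefix as a block edgeR called 10 genes higher and 8 lower.

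Globular embryos were compared with 2-4 cell embryos of the same cross, which follows the embryo as its tissues are laid down. Of 17706 genes tested, 68 rose and 137 fell in the globular library. Patterning genes were among those that rose. PHABULOSA (PHB), a class III HD-ZIP transcription factor of the upper side of organs, was at 268 CPM in the globular library and 31.1 ± 12.6 CPM (SD, n = 2) in WT 2-4 cell embryos (log2 fold change 3.10, SE 0.55, edgeR adjusted p = 0.00837). PLT3, a PLETHORA gene of the root meristem, had 1 read in the WT 2-4 cell libraries and a ratio of 218 (counting interval 37.7 to 8735; edgeR adjusted p = 0.0151). It overlaps an antisense gene and is uncertain. JACKDAW (JKD), a zinc finger factor of ground tissue, was at least 38.1-fold higher. HP6, an inhibitor of cytokinin signalling, was at least 87.4-fold higher. Both had 0 reads in the WT 2-4 cell libraries and are set against a floor of 3 reads per library. On the same footing the sugar transporter gene SWEET9 was at least 124-fold higher, AT1G32583, a gene named for tapetum determination, at least 80.6-fold and the acyltransferase gene AT5G55340 at least 47.0-fold. So were the lipid-binding START domain gene AT5G07260 (at least 43.1-fold), AT1G80450 (at least 39.2-fold), the B3 factor gene AT1G26680 (at least 37.5-fold) and the receptor kinase gene AT5G48940 (at least 32.5-fold). The lipase gene AT5G22810 was at least 440-fold higher, but it overlaps an antisense gene and is uncertain. AT5G48940 no longer passed without WT library 11 (edgeR adjusted p = 0.060). JKD, AT1G26680 and AT5G48940 did not pass with the name prefix as a block (edgeR adjusted p 0.085 to 0.16), after thinning to equal depth (0.057 to 0.073) or with isoforms summed (0.053 to 0.087), and AT1G32583 did not pass by DESeq2 (0.056).

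Several of the genes that fell at the globular stage had no reads in the globular library. ARGAH2, an arginase, was at 169 ± 133 CPM in WT 2-4 cell embryos and without reads in the globular library, at least 94.8-fold lower. Also without reads there were the ChaC-like gene AT5G26220 (at least 62.9-fold lower), AT4G23350 (38.8-fold), the small chaperone gene AT2G29500 (35.1-fold) and AT1G53950 (25.2-fold), each fold being a lower bound. So were AT2G27385 (at least 25.1-fold), the SKU5-similar gene sks8 (at least 22.0-fold) and the calmodulin-like gene CML38 (at least 20.6-fold). HSP17.4 (at least 45.8-fold lower) and AT1G77160 (31.4-fold) are uncertain, the first for an antisense overlap and the second for sequence shared with other loci. In the seed coat library AT4G23350 was at 74.4 CPM, AT2G27385 at 59.2 CPM and sks8 at 47.1 CPM. Their WT 2-4 cell means were 69.1, 44.8 and 39.1 CPM. The other genes listed here were lower in the seed coat library than in WT. Whether less seed coat RNA in the globular library lies behind any of these falls was not tested. The lone globular library was assumed to vary like the 2-4 cell pairs, with 2 residual degrees of freedom. The DESeq2 Wald test called 77 higher and 265 lower. Counts were 108 higher and 289 lower without WT library 7 and 127 and 230 without WT library 11. They were 144 and 336 without kyp library 11 and 160 and 337 without kyp library 12.

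By list, embryo patterning regulators rose at the globular stage, with 29 of 40 tested members positive. The median log2 fold change was 0.74 (0.67 with genes without reads in a group set at their bound; camera adjusted p = 1.0e-04; adjusted p = 0.27 with an estimated correlation). The median was 1.16 without WT library 11. Of these regulators 2 rose over all genes, and 6 rose and 3 fell when adjusted over the list alone. DESeq2 called 2 in each direction. The ribosomal protein list passed on the higher side, with 226 of 294 members positive, 68 negative and a median of 0.40 (camera adjusted p = 2.7e-05; adjusted p = 0.64 with an estimated correlation). By edgeR 0 of the 294 passed over all genes or adjusted over the list alone, 24 were higher and 7 lower at an unadjusted p under 0.05, and DESeq2 called 1 in each direction. The wounding, touch and jasmonate list fell, with 14 of 16 members negative and a median of −3.11 (−2.41 at the bounds; camera adjusted p = 1.5e-10; adjusted p = 0.26 with an estimated correlation). Of its members 4 fell over all genes tested (7 by DESeq2) and 10 when adjusted over the list alone. DREB2A was at 27.9 CPM against 384 ± 41.2 CPM (log2 fold change −3.78, SE 0.57) and JAZ1, a repressor of jasmonate signalling, at 55.2 against 261 ± 3.45 CPM. VSP1, a jasmonate-induced storage protein, was at 2.97 against 37.6 ± 10.8 CPM. WRKY40, a defence transcription factor, had 2 reads and was lower by a ratio of 55.7 (counting interval 15.3 to 461). Heat shock genes fell, with each of the 8 tested negative and a median of −2.67 (−2.13 at the bounds; camera adjusted p = 3.3e-09; adjusted p = 0.26 with an estimated correlation). Among them 4 fell over all genes and 6 adjusted over the list alone. The WT libraries are those of the kyp comparison, where this list also fell. HSFA2 was at 54.6 against 417 ± 131 CPM, HSP17.6A at 4.16 against 75.9 ± 43.5 CPM and HSP70-4 at 44.5 against 236 ± 63.8 CPM. Without WT library 7 the adjusted p was 0.054 for HSP17.6A and 0.060 for HSP70-4. JAZ1, VSP1 and HSP70-4 did not pass after thinning to equal depth (edgeR adjusted p 0.053 to 0.060), nor did JAZ1, HSP17.6A and HSP70-4 with isoforms summed (0.055 to 0.071).

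The remaining lists did not pass in the globular comparison. Ovule integument genes had a median of −0.19 (camera adjusted p = 0.86) and members that went both ways. The vacuolar processing enzyme gene DELTA-VPE, uncertain for an antisense overlap, was at 863 CPM against 80.9 ± 21.3 CPM (log2 fold change 3.42, SE 0.51, edgeR adjusted p = 0.00195). CYP78A5, a growth-promoting cytochrome P450, was at 284 against 1609 ± 597 CPM (−2.50, SE 0.50, edgeR adjusted p = 0.0177). SHP2, a MADS-box gene of ovules that is uncertain for the same reason, was at 29.7 against 199 ± 91.6 CPM (−2.74, SE 0.61, edgeR adjusted p = 0.0348). Adjusted over the list alone 2 of its 18 members rose and 2 fell. Flavonoid genes had a median of −0.38 (camera adjusted p = 0.19), which was −0.65 and past the threshold without WT library 11 (adjusted p = 0.0057). The camera adjusted p was 0.75 for endosperm genes (median 0.09), methylation machinery (−0.16), known methylation targets (−0.17) and photosynthesis genes (0.02). It was 0.49 for CAF-1 and Polycomb complexes (−0.76, or −0.72 at the bounds), 0.19 for cell cycle genes (0.17), 0.32 for reference genes (−0.36) and 0.54 for pseudogene and transposon loci (−0.20, or 0 at the bounds). Within that last class the SADHU1-2 retroposon locus rose, at 100 CPM against 1.97 ± 0.378 CPM (log2 fold change 5.62, SE 0.80, edgeR adjusted p = 0.00184). AT3G17050 fell, lower by a ratio of 45.9 (counting interval 15.6 to 223; edgeR adjusted p = 0.00861). Both also passed when adjusted over the list alone. The single tested storage gene, OLE1 of oil bodies, was at 0 CPM in the globular library and 2.56 ± 3.62 CPM in WT. The pollen genes VGD1 and the LAT52-like gene were at 1.78 CPM each against 3.93 ± 4.35 and 0.420 ± 0.595 CPM.

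The seed coat library was compared with the WT 2-4 cell embryos that develop inside such coats. The seed coat was of Ler alone and the embryos also held a Col genome, so tissue and genome cannot be told apart. Of 17706 genes tested, 28 rose and 111 fell in the seed coat. NRT1.7, a nitrate transporter of the phloem, had 1 read in the WT embryo libraries and a ratio of 175 (counting interval 30.3 to 7009.7; edgeR adjusted p = 0.00715). SUC2, the sucrose transporter of phloem companion cells, was at 34.1 CPM in the seed coat and 0.707 ± 0.207 CPM (SD, n = 2) in WT embryos (log2 fold change 5.53, SE 1.01, edgeR adjusted p = 0.0118). BMY3, a beta-amylase gene, was at 812 against 36.8 ± 38.7 CPM (4.44, SE 0.73, edgeR adjusted p = 0.00665). DYL1, a dormancy-associated gene, was at 500 against 19.8 ± 13.6 CPM (4.63, SE 1.03, edgeR adjusted p = 0.0424). The kinase gene WNK1 (log2 fold change 4.97), the terpenoid cyclase gene AT3G14520 (4.68), AT3G28750 (4.65) and AT4G32480 (4.51) rose too. The LAT52-like gene and the glutathione transferase gene GSTU27 had ratios of 60.1 (counting interval 19.7 to 298) and 66.2 (10.8 to 2719). Without WT library 7 the adjusted p of GSTU27 was 0.052. Without WT library 11 the fitted log2 fold change of the LAT52-like gene was 9.18 in place of 5.85. BMY3, AT3G28750 and DYL1 did not pass by DESeq2 (adjusted p = 0.067, 0.21 and 0.34) or by the legacy robust edgeR fit (0.47, 0.52 and 0.83), and AT4G32480 did not pass by the latter (0.058). With isoforms summed AT3G14520, the LAT52-like gene, AT3G28750, GSTU27 and DYL1 did not pass (edgeR adjusted p 0.053 to 0.10), nor did GSTU27 after thinning (0.073) or DYL1 with the prefix block (0.068).

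Embryo regulators were among the genes that fell in the seed coat. PLT2, a PLETHORA gene, and LEC2, a B3 factor of embryo identity, had no reads there and were at least 41.8-fold and 34.5-fold lower, against a floor of 3 reads per library. WOX2, a homeobox gene of the apical embryo lineage, and BBM, an AP2 factor that promotes embryo identity, had 2 reads each and were lower by ratios of 45.3 (counting interval 12.4 to 376) and 44.4 (12.1 to 368). Also without reads in the seed coat were AT5G43240 (at least 87.2-fold lower), the peroxidase gene AT4G31760 (42.7-fold), AT1G56040 (35.98-fold) and AT1G31400 (35.5-fold). So were AT1G53950 (33.3-fold), AT5G62800 (32.4-fold), AT3G50030 (31.7-fold) and AT1G77160 (41.7-fold, uncertain for sequence shared with other loci), each fold being a lower bound. With isoforms summed LEC2 and BBM did not pass (edgeR adjusted p = 0.052 and 0.053). Because the seed coat was of Ler alone, a gene without reads there may differ by genome and not by tissue, which was not tested. The lone seed coat library was assumed to vary like the 2-4 cell pairs. The DESeq2 Wald test called 47 genes higher and 395 lower. Counts were 51 higher and 242 lower without WT library 7 and 113 and 176 without WT library 11. They were 107 and 279 without kyp library 11 and 134 and 294 without kyp library 12.

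By list, photosynthesis genes rose in the seed coat, with each of the 38 tested positive. The median log2 fold change was 2.13 (camera adjusted p = 3.4e-33; adjusted p = 0.25 with an estimated correlation). Of these 5 rose over all genes (13 by DESeq2) and 30 adjusted over the list alone. Among antenna proteins of the photosystems, LHCB5 was at 152 against 10.4 ± 1.99 CPM and LHCA3 at 189 against 17.3 ± 4.01 CPM. LHCA4 was at 385 against 49.8 ± 1.67 CPM and LHCB4.1 at 201 against 29.7 ± 5.18 CPM. LHCB4.1 did not pass with isoforms summed (edgeR adjusted p = 0.056). The endosperm and imprinted gene list passed on the higher side with a median of 1.04, 16 of 20 positive (camera adjusted p = 0.021; adjusted p = 0.44 with an estimated correlation). The call was lost without kyp library 11 (median 0.94, adjusted p = 0.062) and without WT library 11 (0.60, 0.14). It was also lost without a low-count filter (0.93, 0.11) and with the name prefix as a block (0.28, 0.12). By edgeR 0 of these 20 passed over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 called 0.

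Lists for ribosomal proteins, the cell cycle, patterning, methylation and heat shock fell in the seed coat. Ribosomal protein genes had 245 of 294 negative and a median of −0.94 (camera adjusted p = 1.6e-19; adjusted p = 0.24 with an estimated correlation). Over all genes 2 fell, AT3G58660 (144 against 819 ± 228 CPM) and AT3G16780 (204 against 899 ± 210 CPM). Adjusted over the list alone 31 fell and 1 rose. At an unadjusted p under 0.05 there were 120 lower and 3 higher, and DESeq2 called 57 lower. AT3G16780 did not pass after thinning (edgeR adjusted p = 0.052) or with isoforms summed (0.069). Cell cycle and DNA replication genes had 30 of 34 negative and a median of −0.90 (camera adjusted p = 1.2e-05; adjusted p = 0.23 with an estimated correlation). In it 1 fell adjusted over the list alone. Over all genes edgeR called 0 of the 34, against 7 lower at an unadjusted p under 0.05 and 1 by DESeq2. Embryo patterning regulators fell, 28 of 40 negative with a median of −0.47 (−0.39 at the bounds; camera adjusted p = 3.8e-06; adjusted p = 0.23 with an estimated correlation). Of these 5 fell over all genes and 9 adjusted over the list alone. The machinery of H3K9 and DNA methylation fell, 23 of 29 negative with a median of −0.51 (camera adjusted p = 0.0012; adjusted p = 0.23 with an estimated correlation). Of these 1 fell adjusted over the list alone. Over all genes edgeR called 0 of the 29, against 3 lower at an unadjusted p under 0.05 and 1 by DESeq2. Heat shock genes fell, each of the 8 tested negative with a median of −4.09 (camera adjusted p = 7.4e-18; adjusted p = 0.23 with an estimated correlation). Of them 5 fell over all genes and 7 adjusted over the list alone. The WT libraries are again those of the kyp and globular comparisons. HSFA2 was at 25.1 against 417 ± 131 CPM and HSP70-4 at 13.4 against 236 ± 63.8 CPM. HSP17.6A had 1 read there and was lower by a ratio of 155 (counting interval 27.7 to 6142), and HSP17.6II, without reads, was at least 26.5-fold lower. Pseudogene and transposon loci fell with a median of −0.43 (−0.14 at the bounds; camera adjusted p = 0.019; adjusted p = 0.44 with an estimated correlation). The call was lost without WT library 11 (median 0.00, adjusted p = 0.21), without a low-count filter (0.26) and with the prefix block (0.22). The median was −0.66 without kyp library 12. Of this class edgeR called 0 over all genes, 3 were higher and 14 lower at an unadjusted p under 0.05, DESeq2 called 3 lower, and 2 fell adjusted over the list alone.

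The seed coat lists did not separate the seed coat library from the WT embryos. Flavonoid and proanthocyanidin genes, which make seed coat pigment, had a median log2 fold change of 0.10 (camera adjusted p = 0.69, and 0.027 with a median of 0.42 without WT library 7). TT4, chalcone synthase, was at 2696 CPM in the seed coat and 3352 ± 2277 CPM in WT embryos. Ovule integument genes had a median of 0.31 and a mean of −0.09 (camera adjusted p = 0.96). CYP78A5 fell, at 58.7 against 1609 ± 597 CPM (−4.78, SE 0.57, edgeR adjusted p = 5.2e-04), with 2 members lower adjusted over the list alone. Wounding genes (median −0.49, camera adjusted p = 0.11), CAF-1 and Polycomb complexes (−0.34, 0.43), known methylation targets (−0.31, 0.68) and reference genes (−0.40, 0.29) did not pass. Of the 2 tested pollen genes the LAT52-like gene rose over all genes and adjusted over the list alone, and OLE1, the tested storage gene, had no reads in the seed coat library.

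Each embryo library was then set against the seed coat library for the levels of seed coat transcripts. Over 37 flavonoid and integument genes with at least 10 reads in the seed coat, the median ratio of embryo to seed coat CPM was 0.872 in WT library 7 (95% order-statistic interval over genes 0.703 to 1.12) and 0.585 in WT library 11 (0.496 to 0.670). It was 0.767 in kyp library 11 (0.620 to 0.850), 0.896 in kyp library 12 (0.767 to 1.07) and 0.585 in the globular library (0.467 to 0.820). For photosynthesis genes the median ratio was 0.143 and 0.183 in WT libraries 7 and 11, 0.684 and 0.227 in kyp libraries 11 and 12 and 0.174 in the globular library. Reference genes had median ratios between 0.713 (globular) and 1.06 (WT library 7). Across 17706 genes, which are not independent, the correlation of log2 CPM with the seed coat library was 0.842 for kyp library 11 and 0.823 for kyp library 12. It was 0.819 and 0.811 for WT libraries 7 and 11 and 0.751 for the globular library.

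**Figure D3:**
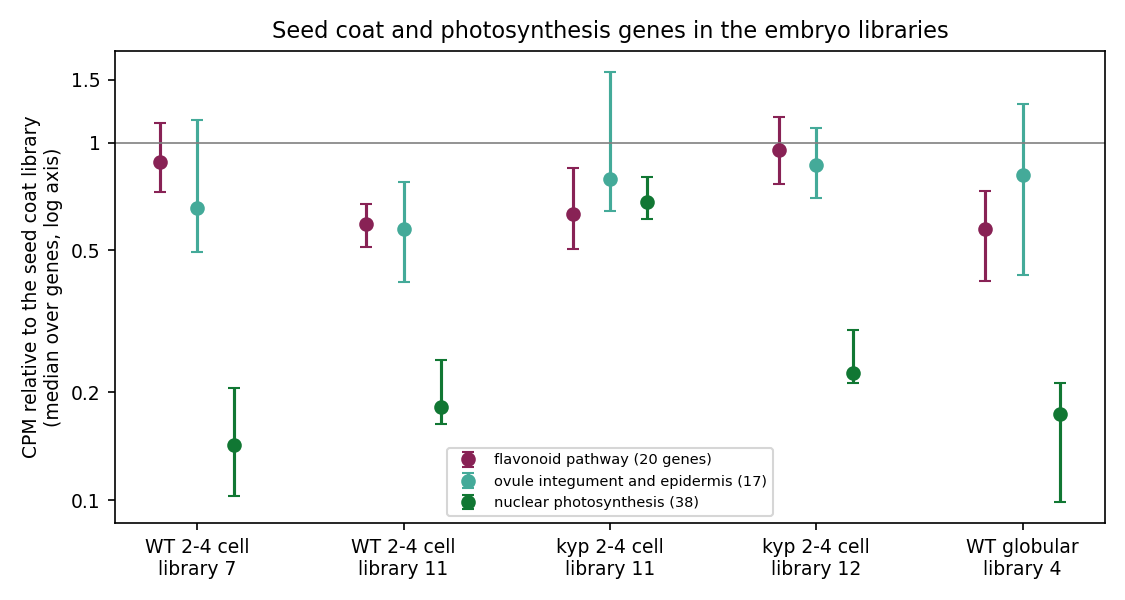
Median ratio, on a log axis, of CPM in each embryo library to CPM in the seed coat library for the flavonoid, ovule integument and photosynthesis lists, with bars for the 95% order-statistic interval over genes and a line at a ratio of 1. Flavonoid genes had medians between 0.572 (globular) and 0.957 (kyp library 12), and photosynthesis genes between 0.143 (WT library 7) and 0.684 (kyp library 11).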

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

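The isoform choices, and the pseudogene class without its called locus, were alternatives chosen after the results were seen. No named gene call turned its direction where it was tested under an alternative. Among list calls the median of the kyp pseudogene class turned to −0.06 without kyp library 12 (54 positive, 57 negative), and that of the seed coat call of the class was 0.00 without WT library 11 and without a low-count filter. The 5 genes called in the kyp comparison passed under each alternative, except AT2G20460 when reads were thinned to equal depth (adjusted p = 0.067). Of the list results 612 kept their side of the threshold, 40 were lost and 6 gained, and of the named gene results 2108, 40 and 93. Other scalings, the prefix block and thinning moved the median of all genes by at most 0.033 on the log2 scale. No camera call held with an estimated inter-gene correlation, a setting whose power to call a changed list was not tested. The pseudogene class stayed past the threshold without its called locus. Lists were not tested by the DESeq2 Wald test, and the parental allele share was not run. By sample number no paired analysis was possible because the WT and kyp groups share only 1 number, and the libraries were instead paired by name prefix, as differences within each pair and as a block. Simulated 2-fold changes in genes of at least 20 mean reads were found in 2 to 4% of cases, and how much of this is due to depth was not tested. Thinned to the lowest depth, the counts were 2 and 2 for kyp, 57 and 109 for globular and 25 and 95 for the seed coat.

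The cause of the following moves was not tested. The DESeq2 Wald test called 33 genes higher and 17 lower in kyp, 265 lower in the globular library, and 47 higher and 395 lower in the seed coat. Without a low-count filter, which tests more genes, the counts were 75 and 31 for kyp, 178 and 384 for globular and 145 and 334 for the seed coat. With the name prefix as a block they were 10 and 8 for kyp, 245 lower for globular, and 52 and 244 for the seed coat. The legacy robust fit gave 8 and 4 for kyp and 177 lower for the seed coat. The fit over all 6 libraries gave 10 and 4 for kyp, and the sum over isoforms 13 and 71 for the seed coat. Leaving out each 2-4 cell library in turn gave 4 to 87 higher and 4 to 48 lower for kyp, 108 to 160 higher and 230 to 337 lower for globular, and 51 to 134 higher and 176 to 294 lower for the seed coat. The seed coat list ratio of WT library 7 was 1.07 with TMM-scaled CPM and 0.657 for the integument list alone, and that of the globular library 0.811 for the integument list alone. The agreement of the kyp minus WT differences stayed between a Pearson correlation of 0.0464 and 0.0581, and with the pairs crossed between −0.0394 and −0.165.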

Other observations

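Summed list levels set the libraries apart in further ways. Ribosomal protein genes took 120234 CPM in the globular library, 97592 and 82195 CPM in WT libraries 7 and 11, 95184 and 79535 CPM in kyp libraries 11 and 12, and 54579 CPM in the seed coat library. Pollen and sperm genes summed to 56.3 CPM in the seed coat library, 47.6 and 33.1 CPM in kyp libraries 11 and 12, 3.4 CPM in the globular library and 1.2 and 7.4 CPM in WT libraries 7 and 11. Of the 5 members only 2, VGD1 and the LAT52-like gene, had at least 10 reads in the seed coat and kyp libraries. The sums rest on these genes and do not show pollen or sperm RNA. Seed storage and oil body genes, which serve the later filling of the seed, stayed between 0 CPM (seed coat) and 10.8 CPM (WT library 7). Splitting the 4 libraries of 2-4 cell embryos by the MC name prefix gave 25 genes past an edgeR adjusted p of 0.05. The split by genotype gave 5, and the crossed split, WT library 7 and kyp library 12 against the others, gave 0. At an unadjusted p under 0.05 the counts were 850, 815 and 589. The libraries with the prefix also hold more reads and fractional values, so this split cannot be told apart from depth or processing.

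Of the tests that follow, those of seed coat RNA behind the photosynthesis genes and of dilution of the heat shock genes at the same share were planned before their results were seen, with a read minimum added after a first look. The others, and the counts of loci over 4-fold, were chosen after the results were seen.

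Seed coat genes stood at median ratios of 0.585 to 0.896 to their seed coat level in the embryo libraries. The intervals ended below that level in WT library 11 (0.670), kyp library 11 (0.850) and the globular library (0.820). They reached it in WT library 7 (1.12) and kyp library 12 (1.07). Whole seed coat RNA in the libraries other than kyp library 11 would bring photosynthesis genes to a like share, and their highest median ratio there was 0.227 (upper bound 0.299). In kyp library 11 photosynthesis genes were high. There 27 genes with at most 3 reads in the seed coat library and at least 50 in the globular library were set against kyp library 12. They lay 0.36 (−0.14 to 0.97) higher on the log2 scale, where the 59.1% of extra seed coat RNA needed would put them at −1.29. These genes were chosen as expressed at the globular stage. The value argues against that share only if no difference in stage between both libraries offset dilution. Set against the reference genes of each library, the ratio stayed at 0.640 or above, which argues against scaling as the cause. That value has no interval, and the reference medians rest on 11 genes (0.468 to 1.07 in the globular library). A candidate explanation left open and untested is RNA from part of the seed coat, such as a layer with few chloroplasts, and another is expression in the embryo itself.

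Pseudogene and transposon loci passed the list test in kyp embryos (camera adjusted p = 0.0010; adjusted p = 0.41 with an estimated correlation), a call lost without WT library 7 (0.070) and without kyp library 12 (median −0.06, 0.85), with 1 of 107 members called over all genes by edgeR, and 9 higher and 1 lower by DESeq2. Of 163 class loci with at least 10 reads in a 2-4 cell library, 13 (7.98%) were over 4-fold higher in kyp within both prefix pairs. Another 4 (2.45%) were over 4-fold lower. But 14 (8.59%) were over 4-fold higher in both libraries with the MC prefix and 1 lower, so the prefix splits the class as much as the genotype does. Among 17672 other genes these shares were 0.76%, 0.36%, 0.76% and, for lower with the prefix, 0.36%. The libraries with the MC prefix also hold more reads, and the part of depth in these counts was not tested. Set against kyp, the class lay at a median of −1.37 (−1.81 to −0.50) in the wild-type seed coat library. The 13 loci, among them AT2G20460, AT1G64270 and AT3G29078, had 0 or 1 read there. Of these, AT1G42705 and AT5G31087 share sequence with other loci and are uncertain. The values speak only to wild-type seed coat RNA, since no seed coat of a kyp-2 mother was sequenced. The class members had also passed a filter on the 4 embryo libraries. The 13 loci were chosen as high in kyp, which favours a lower seed coat level. A single pair of libraries cannot be told apart from the genotype: class loci over 4-fold higher in one pair, chosen on its reads alone, had medians of 1.52 (0 to 4.27) and 0.89 (0 to 1.56) in the other, with bounds that reach 0. A hypothesis that no test here decides is that reduced H3K9 methylation of the maternal genome releases such loci, and a difference between the kyp-2 line and the wild-type Ler stock stays open as well.

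Photosynthesis genes were higher and heat shock genes lower in kyp by camera (adjusted p = 0.47 and 0.36 with an estimated correlation), with 0 of 38 and 0 of 8 passing edgeR over all genes, 17 and 7 at an unadjusted p under 0.05, and 2 and 0 by DESeq2. Whole seed coat RNA as the source would need a 42.0% extra share. Such a share would put 29 genes, chosen by the same read limits in the seed coat and globular libraries, at a median of −0.79. Their observed median was −0.30 (−0.64 to 0.32). If no difference in stage offset dilution, this argues against that share, also behind the heat shock median of −1.39 (−1.60 to −0.10). The criterion planned for dilution, an upper bound of the heat shock median below −0.79, was not met. For a smaller share the bound of −0.64 was taken as the most dilution, but it holds no variation between libraries. Of the 8 heat shock genes 7 lay at −1.34 or lower (exact sign test, two-sided p = 0.0703). That test treats genes from the same 4 libraries as independent, so it does not decide. The upper bound of −0.10, which rests on HSP18.2 alone, also leaves a smaller share open. RNA from part of the seed coat stays open for photosynthesis genes. The 22 tested genes called higher in the seed coat outside that list had medians of 2.95 in the pair with kyp library 11 and 0.47 in the pair with kyp library 12. Genes called higher in the globular library had 0.63 and 0.58, both sets being chosen against the same WT libraries. Without those, 511 genes over 8-fold higher in the seed coat than in the globular library had 0.66 and 0.01. The reverse set of 193 genes had 0.34 and −0.44. Most of the photosynthesis difference may come from 1 library, as the median was 0.299 without kyp library 11, 0.234 of its value with all 4. The heat shock median was −0.946 at the least with a library left out, so no single library gives most of it. The list also fell in the globular and seed coat comparisons, which share the WT libraries. Its summed level was highest in WT libraries 7 and 11 (1476 and 915 CPM). It was 423 and 551 CPM in kyp libraries 11 and 12, 268 CPM in the globular and 148 CPM in the seed coat library. A raised level in the WT pair cannot be told apart from a fall in kyp.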
